A study of Mus musculus with 15 samples.

How the data were processed

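Total RNA from micropunches of mouse prefrontal cortex was sequenced on a BGISEQ-500 instrument, with 15 libraries in 2 groups named by the sample titles, 7 WT and 8 KO. The deposited table gives TPM values, which are length-scaled transcript abundances, per gene and library, and each library summed to between 999789 and 999899. Per the submitters' processing notes, Trimmomatic, HISAT2 and StringTie were used with the mm10 build. Their versions, parameters, strand setting and gene annotation are not given in the sources used here. TPM divides by transcript length and by the library's total, so it keeps no read depth, and a rise in a few abundant transcripts lowers all other values of a library. For that reason no count model was used, precision was taken from the spread between libraries, and 2 other scalings were tried.

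The table held 54838 rows of Ensembl gene IDs. GENCODE M21 symbols and mm10 coordinates matched 54723 of them, 115 had no symbol and kept their ID, and 102 rows were merged by summing the TPM of IDs that share a symbol, which left 54736 genes. Genes with a mean of at least 1 TPM over the 15 libraries were tested, 18656 in all. Values were analysed as log2(TPM + 1). A fold change on this scale understates the change of genes with low TPM. KO was compared with WT in R 4.3.3 with limma 3.58.1 (moderated test with an intensity trend, two-sided), and p-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold.

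Fixed before the data were examined were the gene test, the camera test of the lists and the exact test of the deleted-interval mean. So were the 29 gene lists, the rule for named genes and most alternative settings. The exact test of the scores of the other lists was not among the fixed tests, and when it was chosen is not recorded. The lists covered the deleted interval and the genes beside it, astrocyte, reactive astrocyte, oligodendrocyte, oligodendrocyte precursor, microglia, endothelial, mural, meningeal, choroid plexus and blood markers, striatal, excitatory and inhibitory neuron markers, excitatory and inhibitory synapse, presynaptic, cholinergic and perineuronal net genes, and genes of 9 states or machineries of the cell. Named were the deleted genes and tested neighbours, the 20 genes of lowest p outside the interval (since fewer than 20 passed), 13 fixed names from Gfap to Vip, up to 4 lowest-p members of the lists that answer the study's title and up to 3 of each other called list, and list members that passed over all genes. Egfl7 among the endothelial markers and Gm20457, Gm44718, Gm5898 and Gm7482 inside the interval were named after their values were seen. So were Arhgap17, Pcsk6, Pisd-ps1, Slc26a4, Tm2d3 and the 11 genes at the head of the table.

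Each list was tested with camera at a preset correlation between genes of 0.01 and adjusted over the 29 lists, and again with a correlation estimated from the data and with fry. The mean log2(TPM + 1) of each list per library, called its score, was compared between the groups by an exact two-sided permutation test over all 6435 splits, also adjusted over the 29 lists. The SE of a list mean is that of the difference between group means of the scores. Score differences with a covariate were tested by permuting residuals 100000 times. Counts were compared with 100 splits of the libraries, the real one included.

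The alternatives set in advance were pseudocounts of 0.1 and 0.5, no filter and a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, array weights, a variance prior without trend or with robust fitting, the replicate number as a block, each library left out in turn, the other set tests, deleted genes left out of the count or of other lists, and the row with the highest mean kept for shared symbols. Added after seeing the data were the removal of trends on transcript length and GC content within each library, and a fit without KO 1 and KO 8. The gene test was tested on simulated data of the KO minus WT comparison over 18656 genes, each drawn independently, with 50 genes changed per fold. It recovered 82% of genes at 0.5-fold, 44% at 0.7-fold, 44% at 1.4-fold and 84% at 2-fold, with 10 calls among unchanged genes. Genes in the real libraries are not independent, so these rates may not hold for them. The list test, tested on simulated independent genes, called the shifted list and 1 of 28 others. Raw reads were not used here, and 1 gene that the rule names is not reported here.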

Results

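RNA was sequenced from micropunches of the medial prefrontal cortex of male C57BL/6 mice aged 8 to 10 weeks. Df(h15q13)/+ mice, which lack 1 copy of the chromosome 7 segment that corresponds to the human 15q13 microdeletion, were compared with wild-type littermates. The sample titles gave 7 WT libraries and 8 KO libraries, and KO stands here for these heterozygous animals. The design text of the series gave the numbers the other way round, 7 deletion and 8 wild-type mice. The titles were used, and expression of the deleted genes separated the libraries as the titles named them. Each library was taken as 1 mouse from the series' numbers of animals; the labels name no individual animals, so the p-values measure the spread between libraries. Between 18375 and 18748 genes per library reached 1 TPM, and genes with an mt- symbol held 18.9% to 26.0% of the TPM of a library. Mitochondrial reads assigned to genes with other symbols, if any, are not in this share. Pairwise correlations over genes lay between 0.945 and 0.982, and no pair of libraries was identical. The library with the highest score on the leading principal component, which held 19.3% of the variance, was KO 1 at 51.8, followed by KO 3 at 20.6. TPM values keep no sequencing depth, so the depth behind each value is unknown and no counting interval is given.

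The deleted genes were examined before all others, because they check the labels. Chrna7, Otud7a, Klf13, Mtmr10 and Fan1 all fell in KO cortex to 38.7% to 48.4% of the WT mean, and for each of the 5 genes all 8 KO libraries lay below the WT mean. Klf13, a Krüppel-like transcription factor (ENSMUSG00000052040, chromosome 7, 63886351 to 63938915, mm10), fell from 71.9 ± 8.17 TPM (SD, n = 7) to 34.8 ± 2.96 TPM (SD, n = 8), a log2 fold change of -1.02 ± 0.08 (SE; limma, Benjamini-Hochberg adjusted p = 2.04e-06). Otud7a, which encodes a deubiquitinase (ENSMUSG00000033510, 63444751 to 63759028), fell from 27.1 ± 4.12 to 11.9 ± 1.66 TPM (SD), with a log2 fold change of -1.12 ± 0.10 (SE; limma adjusted p = 4.15e-05). Chrna7, the gene of the α7 nicotinic acetylcholine receptor subunit (ENSMUSG00000030525, 63098692 to 63212569), fell from 9.65 ± 1.24 to 4.49 ± 1.04 TPM, with a log2 fold change of -0.97 ± 0.12 (limma adjusted p = 0.00136). Mtmr10, a myotubularin-related gene (ENSMUSG00000030522, 64287653 to 64340806), fell from 7.86 ± 1.02 to 3.04 ± 0.308 TPM, with a log2 fold change of -1.13 ± 0.08 (limma adjusted p = 2.04e-06). Fan1, a DNA repair nuclease (ENSMUSG00000033458, 64346758 to 64374095), fell from 3.14 ± 0.465 to 1.36 ± 0.400 TPM, with a log2 fold change of -0.83 ± 0.12 (limma adjusted p = 0.00792). Trpm1, an ion channel gene (ENSMUSG00000030523, 64153835 to 64269775), was listed at 0.289 ± 0.182 TPM in WT and 0.113 ± 0.0799 TPM in KO libraries and was too low to be tested. The mean log2(TPM + 1) of the 5 tested genes was 3.91 ± 0.0915 (SD, n = 7) in WT and 2.90 ± 0.119 (SD, n = 8) in KO libraries, a difference of -1.01 with an exact two-sided permutation p of 0.000155, the smallest that 6435 splits can give. As a list they were called lower by camera (adjusted p = 7.56e-22; adjusted p = 7.92e-05 with an estimated correlation).

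**Figure D1:**
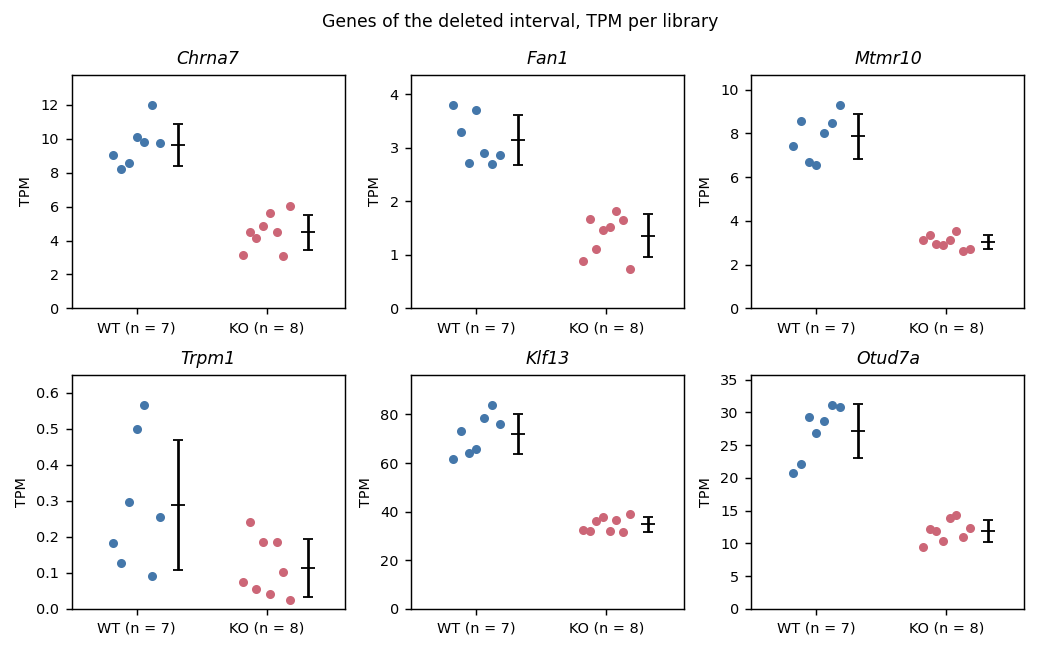
TPM of the deleted genes in each library, with WT and KO side by side, points for single libraries and error bars for the group mean with SD. All 8 KO libraries lay below the WT mean for each of the 5 tested genes, and Klf13 was at 71.9 TPM in WT and 34.8 TPM in KO.

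Against the level that the loss of 1 copy alone would leave, Mtmr10 was lower and the other 4 tested genes could not be told from it. The log2 ratio of observed to copy-number level was -0.37 for Mtmr10 (exact permutation p = 0.00171, adjusted over the 5 genes 0.00855). It was -0.26 for Fan1, -0.18 for Otud7a, -0.13 for Chrna7 and -0.04 for Klf13, with adjusted exact p-values of 0.358, 0.32, 0.48 and 0.55. The annotated transcript Gm20457 lies antisense over the end of Mtmr10 (64337550 to 64345964), and without a statement on strand the reads of these 2 genes cannot be assigned with certainty. Gm20457 itself was lower in KO at a log2 fold change of -0.47, short of the threshold (limma adjusted p = 0.241). The noncoding Gm44718, also inside the interval, had a log2 fold change of -0.59 (adjusted p = 0.291), and the processed pseudogenes Gm5898 and Gm7482 had values of -0.07 and 0.09 (adjusted p = 0.58 and 0.719). Pseudogenes share sequence with genes elsewhere, so their values are uncertain.

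Genes beside the interval did not pass the test, and 6 of the 7 tested ones had higher means in KO. The list of neighbours had a mean log2 difference of 0.157 ± 0.0655 (SE) with all 8 KO libraries above the WT mean (exact permutation p = 0.0334, adjusted over 29 lists 0.0978; camera adjusted p = 0.166). Fam189a1 had the highest value, 0.69 ± 0.29 (SE; limma adjusted p = 0.388), followed by Ndn, an imprinted gene, at 0.35 ± 0.14 (adjusted p = 0.388). Mcee and Nsmce3 were at 0.16 and 0.15, Mphosph10 at 0.06 and Apba2 at 0.01, a value that turned negative under both other scalings. Tjp1, which encodes a tight junction protein, was the 1 lower neighbour, at -0.31 ± 0.11 (adjusted p = 0.338). Within 5 Mb on either side, 65 genes outside the interval were tested, 9 had an unadjusted limma p under 0.05 and 0 passed after adjustment.

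**Figure D2:**
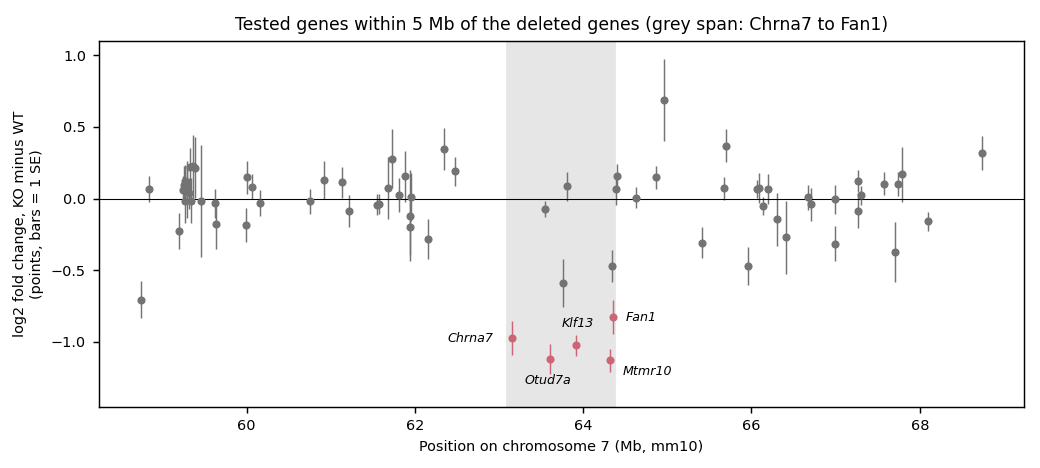
Log2 fold change (KO minus WT, bars 1 SE) of each tested gene against its position on chromosome 7 in Mb (mm10), with the span from Chrna7 to Fan1 shaded. The 5 deleted genes lie between -0.83 and -1.13, below all other tested genes within 5 Mb.

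Across 18656 tested genes the deleted genes were the only ones that passed, in the fit of all libraries to the values as deposited: 5 genes fell and 0 rose (limma, Benjamini-Hochberg). Outside the interval 0 genes passed, while 2219 genes in all had an unadjusted limma p under 0.05, 1060 higher and 1159 lower, against 933 expected by chance. Of the 20 genes outside the interval with the lowest p, 17 were lower and 3 were higher, with all 8 KO libraries on the same side of the WT mean for each gene; all 20 missed the threshold, with adjusted p-values from 0.135 to 0.224. Of the 17 lower ones, 5 were in the endothelial or mural lists. Flt1 and Flt4, which encode receptors for vascular endothelial growth factors, had log2 fold changes of -0.72 ± 0.15 and -0.38 ± 0.08 (SE). The endothelial cadherin gene Cdh5 had -0.57 ± 0.12, the endothelial adhesion gene Esam -0.37 ± 0.08, the adhesion receptor gene Adgrf5 -0.71 ± 0.14 and the thyroid hormone transporter gene Slco1c1 -0.44 ± 0.09. Myh11, the smooth muscle myosin heavy chain gene, had -0.66 ± 0.13, the elastic fibre gene Fbln5 -0.77 ± 0.16 and the secreted protease gene Adamts1 -0.87 ± 0.18. The lipid flippase gene Atp10a had the lowest p, with 7.09 ± 1.79 TPM in WT and 3.87 ± 0.507 TPM in KO (log2 fold change -0.70 ± 0.13, adjusted p = 0.135), and the metal transporter gene Slc39a8 followed with -0.63 ± 0.12 (adjusted p = 0.204). Eps8, Triobp, Gm42738, Pon2, Sema3g and Casp8 had values of -0.48, -0.58, -0.62, -0.31, -0.42 and -0.40. The 3 higher genes were Amn1 at 0.93 ± 0.20, Lhfpl5 at 0.61 ± 0.13 and Gm43206, a transcript of uncertain status, at 0.91 ± 0.19. Leaving out 1 library brought 1 outside gene past the threshold in 5 of 15 fits, for example Atp10a without WT 4 (adjusted p = 0.0099).

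Astrocyte markers were lower as a group in KO cortex, the cell type that the series title names. Of 32 tested markers 29 were lower, 15 of them at an unadjusted p under 0.05, and the mean over the list was -0.22 ± 0.0683 (SE), which is 85.9% of WT, with all 8 KO libraries below the WT mean. Glul, the glutamine synthetase gene, had a log2 fold change of -0.25 ± 0.06 (SE), from 871 ± 57.5 to 734 ± 62.2 TPM. The bicarbonate transporter gene Slc4a4 had -0.54 ± 0.16, Mlc1 -0.21 ± 0.06, Fam107a -0.36 ± 0.11 and the glutamate transporter gene Slc1a3 -0.22 ± 0.07. These 5 genes passed when adjusted over the list alone, and 0 passed over all genes. The glutamate transporter gene Slc1a2 had -0.35 ± 0.13, the water channel gene Aqp4 -0.38 ± 0.14, Aldh1l1 -0.26 ± 0.15 and S100b -0.04 ± 0.09. Gfap, the intermediate filament gene, was at 57.1 ± 16.0 TPM in WT and 38.0 ± 17.1 TPM in KO, a value of -0.66 ± 0.26 (adjusted p = 0.379). The list was called lower by camera with a preset correlation (adjusted p = 2.63e-11; adjusted p = 0.128 with an estimated correlation), and the exact permutation test of the per-library list mean gave p = 0.00513, adjusted 0.0352. The adjusted exact p for the score of astrocyte markers, as this per-library mean is called, was 0.0653 with a filter at a mean of 5 TPM (score difference -0.21), 0.0676 with median-of-ratios scaling and 0.0691 with quantile normalization. It was 0.0913 without KO 1 and KO 8, a setting chosen after seeing the data. The call was also lost in 9 of 15 fits without 1 library, those without WT 1, WT 2, WT 5, WT 6, WT 7, KO 1, KO 2, KO 4 or KO 8, with 0.0773 as the highest value, without WT 5. Reactive astrocyte genes had a median of -0.23, with 15 of 23 lower. At an unadjusted limma p under 0.05, 8 were lower and 2 were higher. Of the lower ones, 2 (Tm4sf1 at -0.38 and Emp1 at -0.52) were past the threshold when adjusted over the list alone and 0 over all genes, and Cd14 was at -0.31. Camera called the reactive list lower (adjusted p = 0.0024; adjusted p = 0.271 with an estimated correlation), while the adjusted exact p was 0.198.

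Vessel markers were lower in the same libraries. Endothelial genes fell: 17 of 18 were lower, 15 of them past the threshold when adjusted over the list alone and 0 over all genes, and the list mean was -0.448 ± 0.106 (SE), 73.3% of WT, with all 8 KO libraries below the WT mean. Flt1 went from 27.8 ± 4.03 to 16.9 ± 4.47 TPM, Cdh5 from 9.75 ± 1.61 to 6.28 ± 1.37 TPM and Slco1c1 from 33.0 ± 3.76 to 24.1 ± 3.37 TPM (SD; limma adjusted p = 0.206 for each over all genes). Egfl7 was the 1 endothelial marker with a higher mean, at 0.01. Genes of mural cells, the pericytes and smooth muscle of vessels, were lower in all 11 cases, with a mean of -0.339 ± 0.102 (SE), 79.1% of WT, and 6 of them passed when adjusted over the list alone and 0 over all genes. Among them Myh11 was at -0.66, the smooth muscle actin gene Acta2 at -0.63 and the pericyte gene Rgs5 at -0.35. Camera called both lists lower (endothelial adjusted p = 2.28e-17, mural adjusted p = 9.63e-07), but with an estimated correlation the adjusted p was 0.088 for endothelial and 0.128 for mural genes. The adjusted exact permutation p was 0.018 for the endothelial mean and 0.0398 for the mural mean. For the score of mural cell markers the call was lost with a filter at a mean of 5 TPM (score difference -0.376, adjusted exact p = 0.0845), with median-of-ratios scaling (0.0532) and without KO 1 and KO 8 (0.101), and in 13 of 15 fits without 1 library, all but those without WT 3 or KO 7 (highest adjusted exact p = 0.0821, without WT 5).

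**Figure D3:**
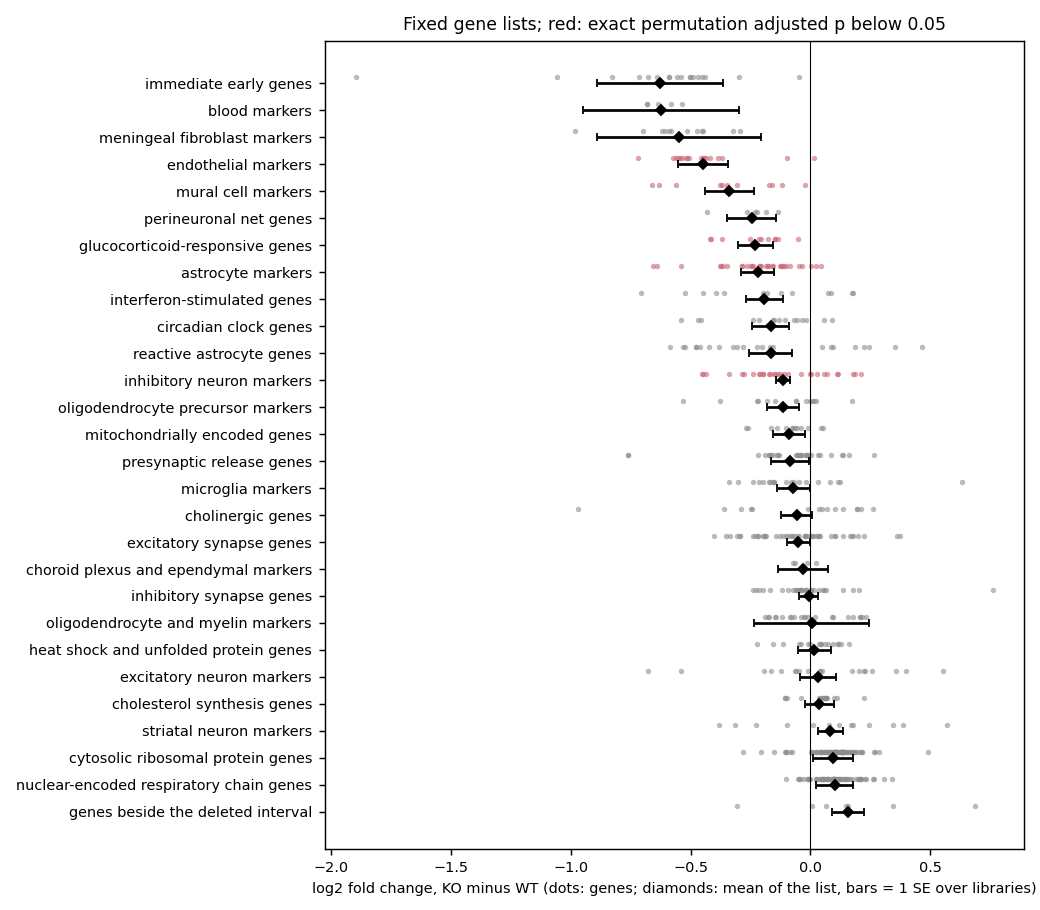
Log2 fold change (KO minus WT) of the tested members of each fixed gene list other than the deleted genes, one dot per gene, with the mean of the list as a diamond and bars of 1 SE over libraries. Lists in red had an exact permutation adjusted p under 0.05, with endothelial markers at -0.448 and astrocyte markers at -0.22.

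Most other non-neuronal lists were lower by less or with a wide spread between libraries, and none of the others had an adjusted exact permutation p under 0.05. Oligodendrocyte precursor markers had a median of -0.06, with 10 of 14 lower, led by Cspg4 at -0.53, Olig2 at -0.22 and Tmem100 at -0.18; camera called the list lower (adjusted p = 0.00811; adjusted p = 0.271 with an estimated correlation). The median of the oligodendrocyte precursor markers list moved with single libraries, to -0.0397 without WT 1, -0.0405 without WT 6 and -0.0398 without KO 2, and to -0.111 without WT 3, -0.0946 without WT 4, -0.12 without KO 1 and -0.112 without KO 8, with the call kept in each of these fits. It was -0.188 without KO 1 and KO 8. Microglia markers had a median of -0.13 and a mean of -0.0712 ± 0.0677 (SE), with 15 of 20 lower, including Sall1 at -0.30, Csf1r, the receptor gene for colony stimulating factor, at -0.21 and Ctss at -0.17; camera gave an adjusted p of 0.000832 (adjusted p = 0.271 with an estimated correlation). Without WT 6 the median of the microglia markers list was -0.0729 (adjusted p = 0.00526). All 12 meningeal fibroblast markers were lower, with a mean of -0.549 ± 0.343 (SE) and examples Lum at -0.61, Mgp at -0.62 and Col1a2 at -0.45; camera gave an adjusted p of 8.32e-05 (adjusted p = 0.34 with an estimated correlation). The 5 blood genes had a mean of -0.624 ± 0.325 (SE), with the near-identical globin genes Hba-a1 and Hba-a2 both at -0.68, which cannot be read apart, and Alas2 at -0.54; camera gave an adjusted p of 0.00105 (adjusted p = 0.271 with an estimated correlation). Over these 4 lists 0 genes passed either over all genes or adjusted over the list alone. Oligodendrocyte and myelin markers were not called (camera adjusted p = 0.945), and their median of -0.02 and mean of 0.01 ± 0.24 (SE) differed in sign. Their score was 4.51 in KO 1 and 4.96 in KO 8, against 3.17 to 3.51 in the other 6 KO libraries and 3.47 to 3.85 in WT, so the mean of this list rests on these 2 libraries. Without KO 8 the median was -0.22 and camera called the list lower (adjusted p = 0.0052). Choroid plexus and ependymal markers, of which 4 were tested, had a median of -0.04 (camera adjusted p = 0.779).

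**Figure D4:**
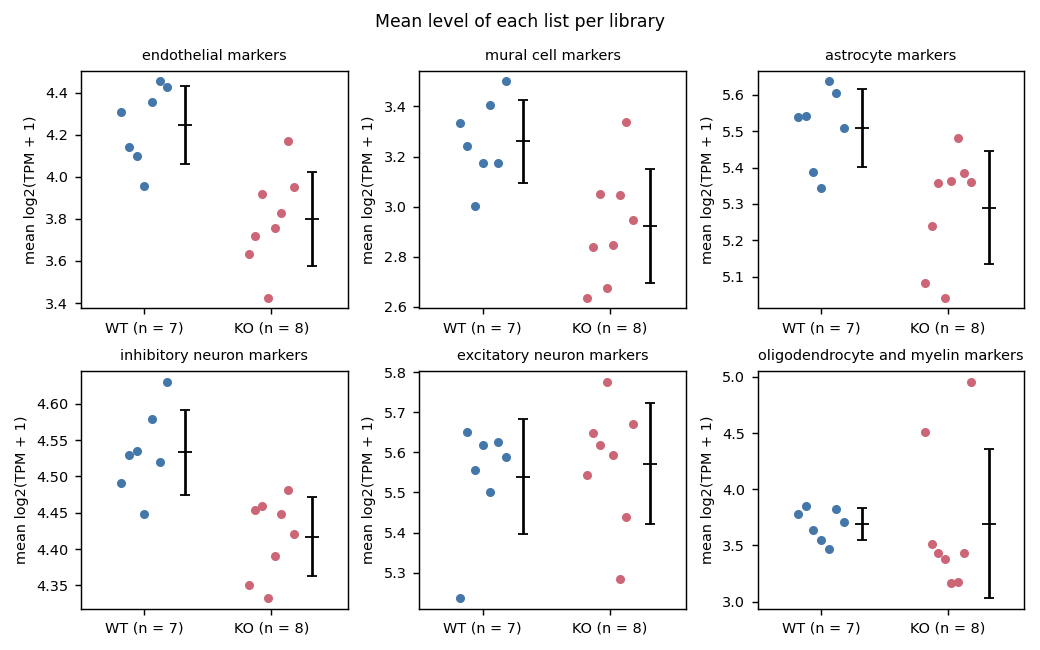
Mean log2(TPM + 1) of the members of selected lists in each library, WT beside KO, with group means and SD. All 8 KO libraries lie below the WT mean for the endothelial, astrocyte and inhibitory neuron lists, and KO 1 and KO 8 stand at 4.51 and 4.96 on the oligodendrocyte list.

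Inhibitory neuron markers fell by a small amount, and excitatory neuron markers were mixed. Of 30 inhibitory markers 21 were lower, with a mean of -0.116 ± 0.0293 (SE), 92.3% of WT, and all 8 KO libraries were below the WT mean. Gad1 and Gad2, the genes of both GABA-synthesizing enzymes, had log2 fold changes of -0.21 ± 0.07 and -0.20 ± 0.07 (SE), the vesicular transporter gene Slc32a1 -0.09 ± 0.09 and the transcription factor gene Maf -0.28 ± 0.10. Of the genes that mark interneuron classes, Pvalb was at -0.44 ± 0.25, Vip at -0.17 ± 0.14 and Sst at 0.11 ± 0.12, none past the test (limma adjusted p = 0.484, 0.598 and 0.704). Camera called the list lower (adjusted p = 0.000309), a call that held with an estimated correlation (adjusted p = 0.0426), and the adjusted exact permutation p was 0.018; 0 genes passed over all genes or adjusted over the list alone. In the same libraries the endothelial and astrocyte means stood at -0.448 and -0.22. Excitatory neuron markers had a median of 0.04, with 11 of 20 higher, and were not called (camera adjusted p = 0.779); 0 passed over all genes or adjusted over the list alone. Slc17a7, the main vesicular glutamate transporter gene of cortex, had 0.22 ± 0.11 (adjusted p = 0.442) and Neurod2 0.21 ± 0.08, while the upper-layer gene Cux2 had -0.54 ± 0.20, Rspo1 -0.68 ± 0.30 and Camk2a -0.20 ± 0.08. Striatal neuron markers, included because a punch can reach neighbouring tissue, had a median of 0.12 (camera adjusted p = 0.379).

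Synaptic genes, which the series title also names, showed small values in both directions. Excitatory synapse genes had a median of -0.05, with 29 of 47 lower; the metabotropic glutamate receptor genes Grm3 and Grm8 were at -0.29 ± 0.10 and 0.36 ± 0.15 (SE), and the scaffold gene Dlg1 was at -0.22 ± 0.09. Camera called this list lower (adjusted p = 0.035; adjusted p = 0.521 with an estimated correlation), but the call was lost without WT 5, WT 6, KO 1 or KO 7 and the median turned to 0.03 once transcript length and GC trends were removed, a setting chosen after seeing the data. Inhibitory synapse genes were not called, with a median of -0.04 and 18 of 29 lower (camera adjusted p = 0.158), and Glra2, a glycine receptor subunit gene, was at 0.76 ± 0.29. Presynaptic release genes had a median of -0.04 with 21 of 29 lower (camera adjusted p = 0.155). The presynaptic release genes list was called lower without KO 8 (median -0.0811, adjusted p = 0.00635), with quantile normalization (-0.0987, adjusted p = 0.0188) and without KO 1 and KO 8 (-0.0679, adjusted p = 0.0172). Its median was -0.0894 without WT 1, -0.0235 without WT 6 and -0.00112 with length and GC trends removed, with no call. In these 3 lists 0 genes passed over all genes or adjusted over the list alone. Of the synapse lists, the excitatory one shares Camk2a, Slc17a6 and Slc17a7 with the neuron markers, and the inhibitory one also shares members with the inhibitory neuron markers, Gad1 and Gad2 among them. Cholinergic genes were not called (camera adjusted p = 0.466); their median of 0.05 and mean of -0.06 differed in sign, and the deleted gene Chrna7 was the 1 member that passed, over all genes and adjusted over the list alone. Perineuronal net genes, which build the matrix around interneurons, were lower in 6 of 6 cases, with a mean of -0.245 ± 0.102 (SE) and examples Ncan at -0.22, Tnr at -0.23 and Hapln1 at -0.43; camera called them lower (adjusted p = 0.00149; adjusted p = 0.264 with an estimated correlation), and the adjusted exact permutation p was 0.0978.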

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

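The tests chosen only after the result was seen are the removal of length and GC trends, the comparisons of endothelial and astrocyte scores with other non-neuronal scores, the correlations between scores, every value without KO 1 and KO 8, and the use of the highest p without 1 KO library as a test of the endothelial pattern, although leaving out each library was itself set in advance.

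Single libraries far from the others of their group were found for 9 of 258 group values examined, fewer than the 12.9 that chance gives at about 1 in 20 groups. KO 1 accounted for 4 of them. In KO 1, Ndn stood at 151 TPM (67.9 to 97.5 in the other KO libraries), Maf at 9.33 TPM (12.3 to 15.2), Dlg1 at 53.3 TPM (67.2 to 82.1) and the circadian clock score at 5.06 (5.26 to 5.43). Slc39a8 stood at 2.31 TPM in KO 3 (0.936 to 1.46 in the others), and Aldh1l1 at 18 TPM in KO 4 (27.0 to 38.4). The cholinergic score stood at 4.57 in KO 8 (4.04 to 4.26 in the others). In WT 6, Slc17a7 stood at 650 TPM (920 to 1160 in the others), and in WT 1 the excitatory neuron score stood at 5.24 (5.50 to 5.65).

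Lower endothelial markers in KO punches were weighed against 5 technical or sampling explanations. With length and GC trends of the libraries removed the score difference was -0.44 ± 0.104 (SE, exact permutation p = 0.00186). Without any 1 KO library the highest exact p was 0.00408. These values argue against such trends or 1 low KO library as the whole cause. With the ribosomal protein score as a covariate the score difference was -0.415 ± 0.112 (permutation p = 0.00298). That fit assumes a common slope, but the endothelial and ribosomal protein scores had r = -0.807 in WT and -0.0576 in KO libraries. It cannot decide on a drift shared with the ribosomal protein genes, which stays open. With the meningeal fibroblast score as a covariate the score difference was -0.366 ± 0.107 (permutation p = 0.00346). That fit also assumes a common slope, but the endothelial and meningeal fibroblast scores had r = 0.226 in WT and 0.651 in KO libraries. It cannot decide on less meningeal tissue in the KO punches, which stays open. Less of all non-neuronal cells alike is argued against by the microglia score, from which the endothelial score differed by -0.377 ± 0.0979 (exact p = 0.00326; -0.404 and 0.00641 without KO 1 and KO 8), whereas the difference from the mean of oligodendrocyte and microglia scores, -0.415 ± 0.143 (exact p = 0.0155), shrank to -0.254 without KO 1 and KO 8, and that from oligodendrocytes alone, -0.453 ± 0.254 (exact p = 0.131), to -0.105. These last 2 values are given without a test because the libraries were chosen on the oligodendrocyte score, and a decline that endothelial cells and oligodendrocytes share stays open. Fewer vessels or less expression per vessel may also give these values and were not tested, since that needs vessel counts in tissue sections, not analysed here.

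Lower astrocyte markers in KO were weighed in the same way. With length and GC trends removed the score difference was -0.201 ± 0.0641 (SE, exact permutation p = 0.00761), which argues against these trends as the whole cause. With the ribosomal protein score as a covariate it was -0.181 ± 0.0652 (permutation p = 0.00932). The astrocyte and ribosomal protein scores had r = -0.889 in WT and -0.376 in KO libraries. A common slope may not hold, so a drift shared with the ribosomal protein genes stays open. A decline shared with other non-neuronal cells stays open. The difference from the microglia score was -0.149 ± 0.0589 (exact p = 0.0287). Without WT 4, WT 5, WT 7, KO 3 or KO 4 it was -0.134 to -0.123 with an exact p of 0.0501 to 0.0603, so its size changed little. It was -0.155 (exact p = 0.0449) without KO 1 and KO 8. The difference from the oligodendrocyte score was -0.225 ± 0.26 (exact p = 0.446) and turned to 0.143 without KO 1 and KO 8. Fewer astrocytes with unchanged expression in each and lower expression per astrocyte cannot be told apart, because 0 markers departed from the list mean (lowest adjusted p = 0.317) and bulk tissue has no count of cells. The biological difference that the design names, the deletion itself, stays open for both the endothelial and the astrocyte pattern as a hypothesis.

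KO 1 and KO 8 had oligodendrocyte scores of 4.51 and 4.96, above all other libraries. Their punches may have taken in more white matter, for which no test was run, and the difference of that score between groups, 0.01 with all libraries, was -0.175 without KO 8. Comparisons with the oligodendrocyte score rest on these libraries.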

How the results depend on the processing

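Removal of length and GC trends and the fit without KO 1 and KO 8 were chosen only after the data were seen; the oligodendrocyte list is left out of the latter because the libraries were chosen on it, and the cause of each change below was not tested except where fewer genes or libraries enter. The deleted genes kept their direction and passed in each fit that tested them, except Fan1 with the replicate block (-0.77, adjusted p = 0.0946), with 5 genes in all under either other pseudocount, no filter, either other scaling, array weights, both other variance settings and the added trend removal, and 4 with mean TPM of at least 5, which drops Fan1. With the deleted genes left out, 0 genes passed. Genes outside the interval passing ranged from 0 to 1 over fits without 1 library (Atp10a without WT 4, Slc39a8 without KO 3, Arhgap17 without KO 4, Fbln5 without KO 7, Pisd-ps1 without KO 8), and 1 passed without KO 1 and KO 8. Same-numbered libraries did not pair (7 pairs, r of their deviations -0.0425 to 0.122, 1 over 0.1, 0 best with their own number). With the replicate block 8 genes passed, 4 of them outside the interval (Fbln5, Flt1, Gm42738, Slc26a4), 0 list scores passed and the oligodendrocyte score was -0.175; the smallest p of 7 pairs is 0.0156. With the block, camera also called the presynaptic release genes list (-0.0811, adjusted p = 0.00263) and the oligodendrocyte and myelin markers list (-0.22, adjusted p = 0.00318). KO 8 has no WT library of the same number, so it adds nothing to the group difference in this fit. The fit without KO 8 and without the block gave the same medians and the same oligodendrocyte score, and also called both lists. These changes therefore cannot be credited to the block itself. Of 19 lists called, 2 remained with an estimated correlation (deleted genes and inhibitory neuron markers) and 6 were called by fry, and the astrocyte median of -0.195 had an adjusted p of 0.128 with an estimated correlation. The 6 list scores past the exact test became 3 with mean TPM of at least 5 and 3 to 7 without 1 library; 3 were left without WT 2, WT 5, WT 6, WT 7, KO 1, KO 2, KO 4 or KO 8. The endothelial and inhibitory neuron scores kept an adjusted exact p under 0.05 without each library, while the astrocyte, mural and glucocorticoid scores lost it in 9, 13 and 10 of 15 fits. The excitatory synapse median had an adjusted p of 0.0804 with array weights (-0.0323), 0.521 with an estimated correlation and 0.408 with fry (-0.0462 in both), 0.139 without KO 1 and KO 8 (-0.0145), and was 0.0317 with trends removed; without 1 library it ranged from -0.0745 to -0.0092, and its adjusted p was 0.0833 without WT 5, 0.147 without WT 6, 0.132 without KO 1 and 0.117 without KO 7. The interferon list lost its call and turned in sign with mean TPM of at least 5, from a median of -0.183 to 0.0857 (adjusted p = 0.944) and from a score of -0.192 to 0.0269 (0.835). The other changes of sign were of results without a call, apart from the excitatory synapse median. With trends removed, the inhibitory synapse median was 0.0357 and scores were 0.0133 (excitatory synapse), 0.0397 (inhibitory synapse), -0.00101 (heat shock) and -0.00106 (oligodendrocyte). Without KO 1 and KO 8, Sst was -0.0339, medians were -0.00295 (cholesterol), -0.0367 (cholinergic), 0.00392 (choroid plexus), -0.0203 (heat shock) and 0.0184 (inhibitory synapse), and scores were -0.0236 (cholesterol), -0.0264 (heat shock) and 0.0142 (inhibitory synapse). With mean TPM of at least 5, the excitatory neuron and oligodendrocyte scores were -0.00448 and -0.031. With median-of-ratios scaling Apba2 was -0.0107 and the heat shock and oligodendrocyte scores -0.000274 and -0.00952; with quantile normalization these were -0.0235, -0.00286 and -0.00283, and the inhibitory synapse median was called at -0.047 (adjusted p = 0.0332). Pseudocount 0.1 gave an oligodendrocyte score of -0.0052, and the cholinergic score without Chrna7 was 0.00772. Without 1 library, ranges were -0.0193 to 0.0423 for Apba2, -0.000914 to 0.117 for Mphosph10 and -0.0912 to 0.0267 for S100b. They were 0.123 to 0.262 for Slc17a7, -0.224 to -0.0728 for Vip and 0.0376 to 0.164 for Sst. They were -0.154 to -0.061 for Slc32a1, -0.326 to -0.166 for Aldh1l1, -0.314 to -0.166 for mt-Nd5 and -0.571 to -0.29 for Col1a2. Medians ranged from 0.058 to 0.158 (striatal), 0.00924 to 0.122 (cholinergic) and 0.0243 to 0.0752 (cholesterol). They ranged from -0.0584 to 0.00161 (inhibitory synapse), -0.0619 to 0.0196 (choroid plexus), -0.00771 to 0.104 (excitatory neuron), -0.00302 to 0.0679 (heat shock) and -0.22 to 0.0671 (oligodendrocyte, called at -0.22 without KO 8, adjusted p = 0.0052). Scores ranged from -0.106 to -0.0295 (cholinergic), 0.0109 to 0.0631 (cholesterol) and -0.0789 to -0.028 (excitatory synapse). They ranged from -0.133 to -0.0541 (presynaptic), -0.142 to -0.0765 (oligodendrocyte precursor), -0.114 to -0.0397 (microglia), 0.0401 to 0.131 (ribosomal), 0.0505 to 0.139 (respiratory) and -0.112 to -0.0545 (mitochondrially encoded). They ranged from -0.0261 to 0.00941 (inhibitory synapse), -0.0777 to 0.00276 (choroid plexus), -0.0182 to 0.0732 (excitatory neuron), -0.0168 to 0.0496 (heat shock) and -0.175 to 0.0811 (oligodendrocyte). Scaling moved the median of all genes from 0.0195 to 0.00411 or 0.0136. Depth is unknown from TPM, so it sets no stated limit; the median SE of 0.105 does.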

Other observations

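Tests in the paragraphs here that were chosen only after the result was seen are the count of list scores over other splits, the correlations between scores, the comparison of genes within 5 Mb of the deletion and all values from the 11 genes at the head of the table.

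Immediate early genes, which neurons switch on after firing, were lower in all 18 cases, 10 of them at an unadjusted p under 0.05, with a mean of -0.627 ± 0.263 (SE) and 7 of 8 KO libraries below the WT mean. Egr2 went from 15.3 ± 11.6 to 4.63 ± 5.08 TPM (SD), Egr3 had a log2 fold change of -0.71 ± 0.20 and Nr4a1 -0.68 ± 0.25. Circadian clock genes were lower in 13 of 15 cases with a median of -0.13, and Ciart at -0.47 was the 1 gene that passed when adjusted over the list alone, beside Per1 at -0.54 and Per2 at -0.46. Glucocorticoid-responsive genes fell by 0.23 in the mean (SE 0.074), with 11 of 11 lower and all 8 KO libraries below the WT mean, including Sult1a1 at -0.41, Tsc22d3 at -0.37 and Pdk4 at -0.25. Interferon-stimulated genes had a median of -0.18, which turned to 0.0857 with a filter at a mean of 5 TPM, where the camera call ended (adjusted p = 0.944), and Parp14 at -0.45, Oasl2 at -0.40 and Irf7 at -0.71 passed when adjusted over the list alone. In these 4 lists 0 genes passed over all genes, and 0 of the immediate early and glucocorticoid-responsive genes passed adjusted over the list alone. Camera called all 4 lists lower, with adjusted p-values of 1.41e-09, 0.00135, 0.000389 and 0.0031 in the order given, but with an estimated correlation the adjusted p was 0.264, 0.271, 0.128 and 0.271. Single libraries moved 2 of these medians by over 1.5 times with the call kept: that of the circadian clock genes list to -0.0778 without KO 8 and that of the interferon-stimulated genes list to -0.114 without KO 1. Adjusted exact permutation p-values were 0.0978, 0.117, 0.0352 and 0.0978, so the glucocorticoid list alone passed. The score of glucocorticoid-responsive genes lost that call with a filter at a mean of 5 TPM (adjusted exact p = 0.0653), without KO 1 and KO 8 (0.101) and with 10 of the 15 libraries left out in turn. Its difference stayed between -0.265 and -0.187 without 1 library and between -0.248 and -0.22 under the other settings.

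Genes of energy metabolism and protein synthesis had small values that did not pass the exact test. Nuclear-encoded respiratory chain genes were higher in 56 of 66 cases, with a median of 0.10 and examples Ndufb7 at 0.31, Ndufa5 at 0.34 and Atp5j2 at 0.23. Cytosolic ribosomal protein genes were higher in 70 of 78 cases, with a median of 0.11 and examples Rpl7a at 0.49, Rps15a at 0.18 and Rpl13a at 0.17, whose many pseudogene copies make single values uncertain. The 13 mitochondrially encoded genes had a median of -0.07, with mt-Co1 at -0.16, mt-Nd4l at -0.27 and mt-Nd5 at -0.26. Camera called these lists higher, higher and lower (adjusted p = 8.32e-05, 0.000235 and 0.00881; adjusted p = 0.563, 0.601 and 0.526 with an estimated correlation), the adjusted exact permutation p-values were 0.385, 0.408 and 0.347, and 0 genes passed over all genes or adjusted over the list alone. For the nuclear-encoded respiratory chain genes list the median was 0.0473 without KO 1 (adjusted p = 0.00928), and the call was lost without KO 1 and KO 8 (0.0261, adjusted p = 0.165). For the cytosolic ribosomal protein genes list 4 of 8 KO libraries lay above the WT mean, KO 1 had the highest score, and the median was 0.0518 without it (adjusted p = 0.0414) and 0.0525 with length and GC trends removed (adjusted p = 0.0464). For the mitochondrially encoded genes list the camera call was also lost without a filter (adjusted p = 0.145), without KO 1 and KO 8 (0.0992), and without WT 1 (0.17), KO 1 (0.0545) or KO 3 (0.0569). Heat shock and unfolded protein genes (median 0.04) and cholesterol synthesis genes (median 0.06) were not called (camera adjusted p = 0.921 and 0.471). Among KO libraries the endothelial and mural scores went together (Pearson r = 0.918, exact permutation p = 0.00216, adjusted over 12 relations 0.0259; Spearman rho = 0.905, exact permutation p = 0.00456, adjusted 0.0547), and r was 0.844 without the 2 libraries farthest out. Among WT libraries r was 0.598 (exact permutation p = 0.161, adjusted 0.215, Spearman rho = 0.607, exact permutation p = 0.167, adjusted 0.223) and fell to 0.246 without the 2 farthest. The difference between groups was not tested. No other relation of the 12 had an adjusted Pearson p under 0.05. Endothelial and astrocyte scores had r = 0.815 in WT and 0.774 in KO libraries (exact permutation p = 0.0272 and 0.0204, adjusted 0.0544 for both). Without the 2 farthest libraries r was 0.24 and 0.716. The endothelial and astrocyte declines may thus not be separate.

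Random regrouping of the 15 libraries served as a test of chance for the counts. For single genes 1 of 100 splits, the real one included, gave as many as the real 5, and the highest other count was 3. These 5 are the deleted genes, whose fall follows from the genotype. With them left out 0 genes passed, fewer than the 3 of that other split. The count therefore says nothing about genes outside the interval. For list scores past the exact permutation test 1 of 100 splits, the real one included, gave as many as the real 6, with 3 in the highest other. With all libraries this makes chance less likely for the count without excluding it. Some of the scores also move together, such as the endothelial and mural scores in KO libraries (r = 0.918), so the 6 are not separate results. One of the 6 is the deleted interval itself. Without 1 library the count was 3 in 8 of 15 fits (without WT 2, WT 5, WT 6, WT 7, KO 1, KO 2, KO 4 or KO 8). The highest other split of all 15 libraries also gave 3, but other splits were not run with 1 library left out. For lists called by camera with a preset correlation 2 of 100 splits gave at least the real 19, and the highest other split also gave 19. Chance is not excluded for that count, since another split tied it and 1 of the real 19 lists is the deleted interval. The other splits called a median of 8 lists and 99 of them at least 1, so a single call by this test carries little weight. At an unadjusted limma p under 0.05, 2 of 100 splits, the real one included, gave at least the real 2219 genes. The highest other split gave 3667, which points to a structure of the libraries that the groups do not explain.

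A passenger or position effect around the deletion was weighed for chromosome 7. Within 20 Mb of the interval 6 of 334 tested genes (1.80%) had an unadjusted p under 0.01, against 538 of 18313 other genes (2.94%). The odds ratio of 0.604 (95% interval 0.219 to 1.34; Fisher's exact p = 0.321) showed no enrichment over that window. Within 5 Mb, a window compared only after the wider result was seen, it was 3 of 65 genes (4.62%), an odds ratio of 1.6 with a wide interval (0.32 to 4.92; Fisher's exact p = 0.442). These 3 are Atp10a (58656166 to 58829420) and Pcsk6, both lower in KO, and Tm2d3, higher in KO, the last 2 of them named after their values were seen. A position effect within 5 Mb, on these genes or on the list of neighbours, stays open.

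The deposited table lists 11 genes ahead of the rest, which follows the order of gene IDs. They are Axl, Mertk, Nr2e1, Fgd6, Slc9a3r1, Emp2, Slc15a2, Slco1c1, Tlr3, S1pr1 and Tmem100. All 11 were lower in KO, with log2 fold changes from -0.55 to -0.18, unadjusted limma p-values from 0.000202 to 0.0123 and adjusted p-values from 0.206 to 0.339. Slco1c1 and Tmem100 are also in 2 of the fixed lists. Why these genes were moved is not known; if they were picked from these libraries, their shared direction is no independent evidence. An additional value of 0.939 stands in an unnamed column beside Syn1 and equals the ratio of that gene's WT mean to its KO mean.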
